A study of Marchantia polymorpha and Arabidopsis thaliana and Lactuca sativa with 30 samples.

How the data were processed

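RNA was sequenced from 30 samples of 3 plants, of which 16 came from whole gemmalings of the liverwort Marchantia polymorpha, 8 from excised shoots of Arabidopsis thaliana and 6 from excised shoots of lettuce. Gemmalings are young plants grown from gemmae, the clonal propagules of the liverwort. The liverwort samples were the wild-type male strain Tak-1 and gpb1-2, which the labels describe as a null mutant of the G protein beta subunit. Gemmalings were 6 days old and the medium held 2 mM calcium (control) or 0 mM calcium. Arabidopsis Col-0 seedlings, also 6 days old, were moved to 2 or 0 mM calcium, and 4-day-old lettuce seedlings to 2 or 0.15 mM calcium. The labels gave every sample a group, with 4 libraries in each liverwort and Arabidopsis group and 3 in each lettuce group. The liverwort titles carry 0 hr for the control medium and 48 hr for the calcium-free medium, so that medium and hour of harvest cannot be told apart in that species. The labels do not say whether replicates were separate cultures, and p-values therefore measure the spread between these samples, part of which may be technical.

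The deposited count tables, 1 per species, hold whole-number read counts per gene and library with no normalization. Per the submitters' processing notes, reads were aligned with STAR 2.5.3a, and TAIR10 is the build named there for the samples of all 3 species. The counting tool, the annotation and the builds for the liverwort and lettuce are not given in the sources used here, nor is the treatment of reads shared between near-identical genes. Genes in tandem arrays or with close copies (the LEA-like, peroxidase and polyketide synthase arrays of the liverwort, and the PDF1.2/PDF1.3, Rubisco small subunit and KIN1 genes of Arabidopsis) are therefore uncertain as single genes. The authors' deposited tables of changed genes give a log2 fold change, its standard error, a test score and an adjusted p-value for 5 comparisons. In these tables, per the file headers and values, the score of the authors equals the size of the log2 fold change minus 1 (Arabidopsis, lettuce) or 0.58 (liverwort), divided by its standard error, and each listed gene has an adjusted p-value below 0.05. All 30 columns of counts were used.

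Arabidopsis names and coordinates were taken from the TAIR10.1 annotation, in which 32548 of the 34218 gene codes of the count table have a gene. Liverwort names came from the MpTak2_v7.1 gene table through its locus tags, and were used for names and for which genes lie next to each other. Of 20574 liverwort identifiers, 17641 were paired with a locus tag and 3091 with a gene symbol. Liverwort genes with no symbol are given by identifier. As a check of this pairing, 8 symbols of abundant housekeeping proteins had a median expression percentile of 99.6, against 42.7, 47.9, 80.5 and 36.3 when the names were shifted by 1, 5, 25 and 100 genes. Lettuce identifiers (43717) are not paired with names, so at most 2 are printed per direction. No source used pairs genes between species, so such overlaps were not analysed. The gene of the G protein beta subunit is not paired with a symbol in the table used, and was not analysed.

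Genes were filtered with filterByExpr (at least 10 counts in a library of average depth, in as many libraries as a group holds), scaled by TMM and tested with the quasi-likelihood F test of edgeR 4.0.16 (R 4.3.3), with Benjamini-Hochberg adjustment and a threshold of 0.05. The 16 liverwort libraries were fitted together as 4 groups, and Arabidopsis and lettuce were each fitted alone. The difference of the calcium responses of the liverwort genotypes was tested as an interaction contrast. Depth ranged from 16.2 M to 26.9 M counts per library (18.5 M to 26.9 M in the liverwort, 18.9 M to 24.7 M in Arabidopsis and 16.2 M to 26.0 M in lettuce). Tests covered 13404, 19316 and 22575 genes in these species. The common biological coefficient of variation was 0.339 in the liverwort, 0.231 in Arabidopsis and 0.213 in lettuce. CPM values used TMM-scaled library sizes, and gene list scores were means of log2 CPM with a prior count of 2. Folds against a group with no counts were computed against a floor of 3 counts over the group, and ratios to a group with 1 to 3 counts have a 95% Poisson interval. These intervals and floors cover counting error only. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 was used for tables and figures.

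For Arabidopsis, 17 lists of gene codes and 22 lists defined by words in gene descriptions were fixed before the data were examined, as were the comparisons, the tests and most other settings tried. The lists of codes are salicylic acid immunity, pattern-triggered immunity, jasmonate and wounding, calcium transport, calcium sensing, cell wall remodelling, oxidative stress, unfolded protein response, senescence and cell death, photosynthesis, cell division, abscisic acid and dehydration, heterotrimeric G proteins, phosphate starvation, iron homeostasis, heat shock, and root markers as a sign of other tissue. No tested Arabidopsis gene had a description matching the words for polyphenol oxidase, which left 21 description lists. For the liverwort, 56 families with at least 10 tested members were defined from the reference symbols after the tables were opened and before any test. Lists were tested with camera (limma 3.58.1, voom weights) at a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry. Camera compares a list with all other genes, and fry tests whether the genes of a list move, on balance, in 1 direction. Members past the threshold were counted over all genes tested and adjusted over the list alone. Most members of the lists of codes are well-known marker genes, and lists overlap in part.

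Named genes were chosen by a rule. It took up to 6 genes per direction with the largest log2 fold change among those past the threshold whose groups did not overlap and whose mean was at least 5 CPM in the higher group, up to 3 members per direction with the smallest adjusted p-value from each reported list, and the Arabidopsis G protein list whatever its result. It gave 400 genes over the 7 comparisons, counting a gene in each comparison, and 155 of these were picked for the text after their values were seen. Genes named outside the rule are said to be so.

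The tests were checked on simulated counts with 200 changed genes. For calcium in Tak-1 (13249 genes), 54% of genes changed by a log2 of 1 and 84% of those by 2 were called in the right direction. There were 8 false calls. Shares were 26% and 74% with 5 false calls for the interaction (13243). They were 56% and 99% with 8 for Arabidopsis (19227), and 43% and 87.9% with 13 for lettuce (22336). Whether this holds for the uneven liverwort replicates below was not tested.

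The other settings fixed in advance were DESeq2 1.42.0, size factors of the RLE kind, no count filter, a stricter filter of 1 CPM, the fold minimum of the authors' tables (log2 of 0.58 or 1), the replicate number as a block, fits of only the groups compared, a robust fit for the interaction and leaving out each library in turn. After seeing the data, 33 settings of 6 kinds were added, among them the fold minimum inside the test and a term for the replicate sets 1 and 2 against 3 and 4. Same-numbered libraries deviated together in Arabidopsis (correlations of deviations from the group means from 0.200 to 0.592 over 4 numbers). Each of the 4 correlated best with its own number, so by the data, not the labels, the numbers pair the samples there. The main fit ignores this. Between the gpb1-2 groups these correlations were 0.158 to 0.570, but only 2 of 4 numbers correlated best with their own (replicate 1 had 0.405 against 0.515 with another number and replicate 4 had 0.158 against 0.529). Pairing there was not separated from the replicate sets. Replicates of a group differed by far more than counting noise in each of 42 pairs (chi-square per degree of freedom from 6.29 to 285), so none were counted as 1 library.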

Results

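The data were read counts per gene for 30 RNA-seq libraries that set calcium-poor medium against a control medium in 3 land plants. They were the liverwort Marchantia polymorpha (Tak-1 wild type and the G protein beta null mutant gpb1-2, 4 groups of 4 libraries), Arabidopsis thaliana (2 groups of 4) and lettuce (2 groups of 3). Calcium was 2 mM in the control and 0 mM in the test medium, or 0.15 mM for lettuce. Libraries held 16.2 M to 26.9 M counts. The series asks which genes respond to calcium deficiency in each species, and whether the response of the liverwort depends on the G protein beta subunit. In a principal component analysis the first component held 50.6% of the variance in the liverwort, 68.3% in Arabidopsis and 85.0% in lettuce. On it, replicate 1 of Tak-1 at 2 mM lay at -14.7, apart from the others of its group at -93.6, -91.6 and -84.7. In the other 3 liverwort groups, replicates 1 and 2 lay apart from replicates 3 and 4 (chi-square per degree of freedom from 15.1 to 45.2 for pairs within these sets and from 118 to 285 for pairs across them). In Tak-1 at 2 mM replicate 2 lay with replicates 3 and 4 (6.29 and 13.9, against 107 with replicate 1). Liverwort counts are also given for replicates 1 and 2 alone (the first set) and 3 and 4 alone (the second set). In Tak-1 at 2 mM the first set is no close pair, so first-set counts that use that group are no replication.

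In Tak-1, LEA-like genes, named for late embryogenesis abundant proteins of drying tissue, had some of the largest rises at 0 against 2 mM calcium. MpLEA-like35, MpLEA-like36 and MpLEA-like39 had no counts at 2 mM and reached 22.1 ± 14.9, 22.0 ± 14.97 and 11.3 ± 7.20 CPM at 0 mM (SD, n = 4), at least 604-fold, 599-fold and 308-fold higher. MpLEA-like37 was 1004 times higher (95% counting interval 278 to 8290) and MpLEA2 678 times (122 to 26796). MpLEA-like40 rose from 0.0628 ± 0.0981 to 17.9 ± 11.4 CPM (log2 fold change 8.06 ± 1.00 SE, edgeR adjusted p = 0.00127). Of 53 LEA-like genes tested, 30 rose and none fell in edgeR, and adjusted over the list alone 34 rose and 1 fell. The median log2 fold change was 3.14. Within replicates 1 and 2 alone it was 3.93, with 39 of 56 higher and 2 lower, and within replicates 3 and 4 alone 1.76, with 14 of 52 higher and 1 lower. Camera called the family (adjusted p = 1.25e-07, and adjusted p = 0.491 with an estimated correlation). Of the 20 members that have another LEA-like gene within 5 genes of them, 19 rose (median 8.23), against 11 of the 33 without such a neighbour (median 0.52). MpLEA-like37 had counts at 2 mM in replicate 1 alone and MpLEA2 in replicate 3 alone, so their folds have no upper bound without these libraries. The log2 fold change of MpLEA-like40 was 9.70 without 2 mM replicate 1.

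Polyketide and chalcone synthase genes (PKS/CHS), which make the starting compounds of flavonoids and related phenolics, also rose in Tak-1. MpPKS/CHS14 went from 45.8 ± 26.2 to 339 ± 148 CPM (log2 fold change 2.89 ± 0.48, edgeR adjusted p = 0.00361) and MpPKS/CHS10 from 27.9 ± 25.1 to 378 ± 175 CPM (3.76 ± 0.63, edgeR adjusted p = 0.00373). The family had 12 of 21 members higher, 14 adjusted over the list alone, and none lower (camera adjusted p = 5.96e-08, and adjusted p = 0.491 with an estimated correlation). Of 13 WRKY transcription factor genes 8 rose, 10 adjusted over the list alone (camera adjusted p = 1.25e-05, and adjusted p = 0.491 with an estimated correlation). Among them MpWRKY3 rose from 1.85 ± 2.97 to 41.3 ± 3.27 CPM and MpWRKY1 from 86.7 ± 8.25 to 169.9 ± 15.04 CPM. Without 2 mM replicate 1 the log2 fold changes of MpPKS/CHS10 and MpWRKY3 moved to 4.64 and 6.81 (from 3.76 and 4.49). The PKS/CHS count was 9 in the first set and 13 in the second, and the WRKY count 8 and 6. The PKS/CHS count moved to 7 without 2 mM replicate 2, 3 or 4, and the WRKY count to 3 without these or 0 mM replicate 1 or 2. In 2 mM replicate 1 the mean log2 CPM was 4.81 for PKS/CHS against 2.35 to 2.79 in the other 2 mM libraries.

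Some members of further families also rose in Tak-1. GH19 chitinase genes had 5 of 12 members higher, 6 adjusted over the list alone, with MpGH19.8 at 16.4 ± 6.31 and 256 ± 156 CPM and MpGH19.7 at 83.1 ± 29.7 and 286 ± 44.2 CPM in 2 and 0 mM. Dirigent genes (DIR), whose products steer the coupling of lignans, had 15 of 40 higher and 2 lower, and 18 and 3 adjusted over the list alone. MpDIR51 rose from 1.37 ± 2.14 to 98.5 ± 88.5 CPM, MpDIR56 from 11.9 ± 8.58 to 96.0 ± 23.4 CPM, and MpDIR65, without counts at 2 mM, was at least 143-fold higher. Without 2 mM replicate 1 the log2 fold changes of MpDIR51 and MpDIR56 moved to 8.32 and 3.68 (from 6.19 and 3.02). The estimate for MpDIR65 was 1.51 times smaller without 0 mM replicate 2. The GH19 and DIR counts dropped to 3 and 7 without 2 mM replicate 2, 3 or 4 or 0 mM replicate 1 or 2, and GH19 had 8 without 2 mM replicate 1. In the first and the second set GH19 had 6 and 7 higher (1 lower in the first), and DIR 14 and 16 higher and 8 and 3 lower. GH17 glucanase genes had 7 of 21 higher, glutathione S-transferase genes (GST) 8 of 32 higher and 1 lower, and ABCC transporter genes 4 of 15 higher and 1 lower. Their counts of higher genes were 5, 12 and 8 in the first set and 9, 10 and 3 in the second, and GST had 5 lower in the first. Without 2 mM replicate 2, 3 or 4 the higher genes dropped to 3, 2 and 2 for GH17 and to 5 for GST, as did GST without 0 mM replicate 1 or 2. The lower GST gene was lost without these 2 libraries, with 2 lower without 0 mM replicate 4. Among these MpGST27 rose to 62.9 ± 33.2 from 11.0 ± 2.80 CPM and MpABCC6 to 207 ± 79.8 from 36.9 ± 3.85 CPM. Camera called GH19, DIR, GH17, GST and ABCC (adjusted p = 0.00120, 0.00344, 0.00785, 0.0245 and 0.0187), each lost with an estimated correlation (adjusted p = 0.505 for DIR and 0.491 for the others with an estimated correlation). MpLOX5, a lipoxygenase, rose from 2.72 ± 1.86 to 47.9 ± 39.1 CPM. MpCYP821-like, a cytochrome P450 with 5.83-fold more at 0 mM, had the smallest adjusted p of the named genes (edgeR adjusted p = 0.000583).

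Fewer named genes fell in Tak-1 at 0 mM. MCM genes, which encode the helicase that opens DNA for replication, had 5 of 10 members lower, 7 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.00220, and adjusted p = 0.491 with an estimated correlation). MpMCM6 fell from 17.8 ± 4.07 to 8.31 ± 2.62 CPM and MpMCM7 from 16.4 ± 1.96 to 8.24 ± 1.78 CPM. Both lost their call on leaving out 0 mM replicate 1 or 2, and also 2 mM replicate 3 (MpMCM6) or 4 (MpMCM7), with edgeR adjusted p from 0.0503 to 0.0583 for MpMCM6 and from 0.0506 to 0.0614 for MpMCM7. The 5 lower MCM genes dropped to 2 without 2 mM replicate 2 and to 1 or fewer without 2 mM replicate 3 or 4 or 0 mM replicate 1 or 2, with 6 lower in the first set and 1 in the second. The pentatricopeptide repeat genes (PPR), whose products process organelle RNA, had 2 of 71 lower with a median of -0.19 (camera adjusted p = 0.00785, and adjusted p = 0.573 with an estimated correlation). In the first set 21 PPR genes were lower and 1 higher, and both lower genes were lost without any library but 0 mM replicates 3 and 4. The receptor kinase gene MpRLK-Pelle_SD-2b1 fell from 15.4 ± 2.55 to 1.39 ± 0.828 CPM, the transporter gene MpABCG14 from 6.27 ± 0.889 to 0.728 ± 0.585, the peroxidase gene MpPOD35 from 5.71 ± 0.369 to 1.11 ± 0.338 and the auxin-response gene MpSAUR1 from 35.4 ± 11.3 to 7.92 ± 1.08. MpPPO63 fell 6.81-fold and MpLEAL4 4.33-fold. Mp8g17780, which has no symbol, fell from 37.0 ± 27.9 to 0.237 ± 0.321 CPM (log2 fold change -7.32 ± 1.19, edgeR adjusted p = 0.00340), and its log2 fold change was -8.83 without 0 mM replicate 4.

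In all, 1183 genes were higher and 617 lower in Tak-1 at 0 mM than at 2 mM (edgeR quasi-likelihood, Benjamini-Hochberg), of which 1016 and 388 also passed the fold minimum of 0.58 on the log2 scale. In the 29 named genes of this comparison each library of the higher group lay above each library of the lower, an outcome with a chance of 2.86% for a gene without a difference and in part required by the naming rule. Within replicates 1 and 2 alone 2062 genes were higher and 1952 lower, and within replicates 3 and 4 alone 889 and 189. Counts moved to 457 higher and 191 lower without 2 mM replicate 2, 460 and 193 without replicate 3, 473 and 215 without replicate 4, and 529 and 129 without 0 mM replicate 1. They moved to 508 and 157 without 0 mM replicate 2, and 932 lower without 0 mM replicate 4. Medium and hour of harvest cannot be told apart here.

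**Figure D1:**
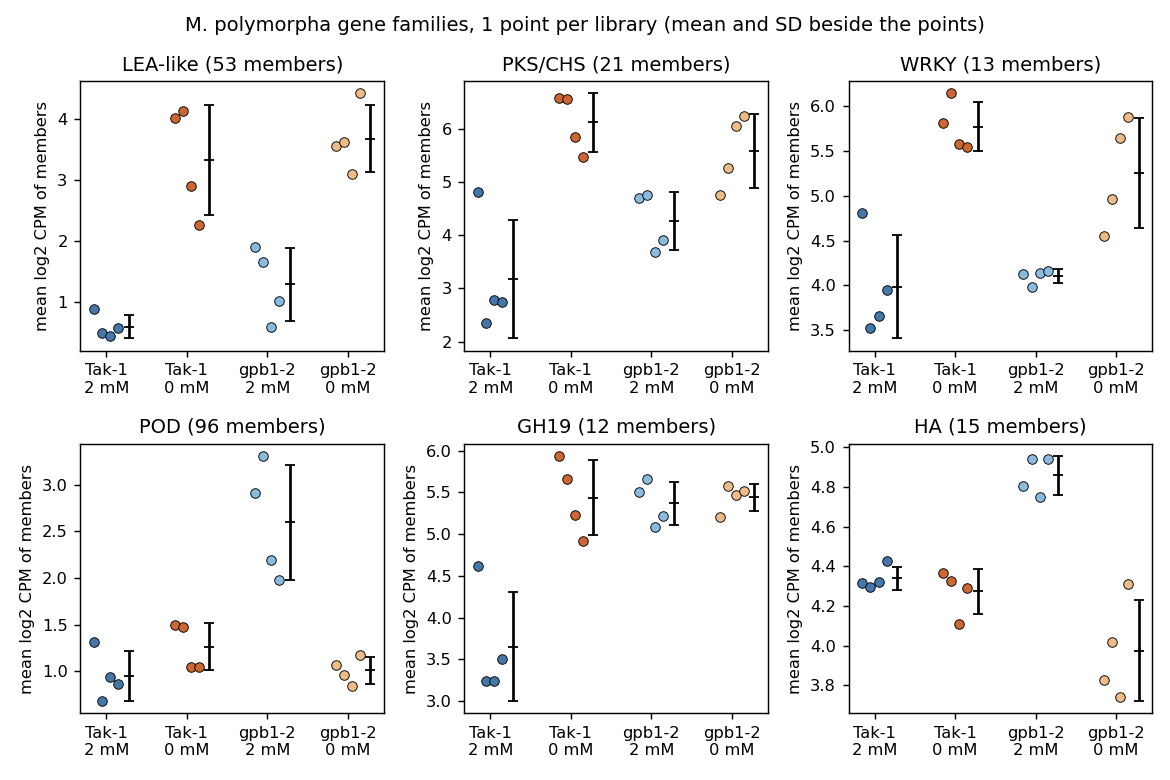
Mean log2 CPM over the tested members of 6 liverwort gene families (y axis) in each library of the 4 groups (x axis, strain and calcium), with the group mean and SD beside the 4 points. LEA-like, PKS/CHS and WRKY scores were higher at 0 mM in both strains, while the POD score was 2.59 ± 0.62 in gpb1-2 at 2 mM and between 0.95 and 1.27 on average in the other groups.

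In gpb1-2, class III peroxidase genes (POD), whose secreted products cross-link and loosen cell walls, were among those that fell at 0 mM against 2 mM. Of 96 members 38 fell and 1 rose, and adjusted over the list alone 57 fell and 4 rose (median log2 fold change -2.23, camera adjusted p = 1.15e-16, and adjusted p = 0.0945 with an estimated correlation). In replicates 1 and 2 alone 34 of 108 were lower and 2 higher (median -2.96), and in replicates 3 and 4 alone 40 of 86 were lower and 9 higher (median -1.74). MpPOD28 fell from 16.1 ± 5.46 to 1.44 ± 0.430 CPM (log2 fold change -3.48 ± 0.31, edgeR adjusted p = 0.000134), MpPOD29 from 14.0 ± 6.24 to 1.66 ± 0.557, MpPOD51 from 21.6 ± 8.74 to 2.90 ± 0.438 and MpPOD130 from 7.24 ± 3.90 to 0.405 ± 0.114. MpPOD34 was 139 times lower (95% counting interval 47.6 to 675), with counts at 0 mM in replicate 1 alone. The member that rose, MpPOD167, went from 169 ± 7.65 to 386 ± 41.5 CPM. Of the 68 members with another peroxidase gene within 5 genes 33 fell, against 5 lower and 1 higher of the 28 others. The summed CPM of those 68 overlapped between media (2522 ± 796 at 2 mM, 3189 ± 245 at 0 mM), so that the most abundant members did not follow the fall.

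Plasma membrane proton pump genes (HA) fell in gpb1-2 in 5 of 15 members, with MpHA13 down from 26.3 ± 15.9 to 3.11 ± 0.953 CPM and the abundant MpHA4 from 995 ± 154 to 558 ± 72.9 CPM (camera adjusted p = 0.00365, and adjusted p = 0.0945 with an estimated correlation). Adjusted over the list alone the count was also 5, and it was 2 in the first set and 5, with 1 higher, in the second. Cellulose synthase-like D genes (CSLD), which act in tip-growing cells, had 3 of 10 lower (2 in the first set, 1 in the second), 4 adjusted over the list alone, with MpCSLD4 falling from 18.5 ± 8.82 to 5.59 ± 1.87 CPM and MpCSLD5 from 4.35 ± 3.44 to 0.495 ± 0.179 CPM, a log2 fold change of -3.12, or -2.44 without 2 mM replicate 2 (camera adjusted p = 0.0405, and adjusted p = 0.287 with an estimated correlation). Camera lost the CSLD call without 2 mM replicate 1 or 2 or 0 mM replicate 1 or 3 (adjusted p from 0.0558 to 0.0990). Expansin genes had 2 of 26 lower (2 in the first set, 5 and 5 higher in the second), 3 adjusted over the list alone, with MpExpansin8 falling from 6.16 ± 1.22 to 2.26 ± 0.702 CPM (camera adjusted p = 0.0461, and adjusted p = 0.586 with an estimated correlation). That family call was lost without 2 mM replicate 1 or 2 or 0 mM replicate 1, 2 or 3 (adjusted p from 0.0651 to 0.175). The pathogenesis-related gene MpPR1l fell 22.3-fold and the dirigent gene MpDIR48 19.77-fold.

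LEA-like genes also rose in gpb1-2, with 23 of 53 higher and 1 lower, and 32 and 2 adjusted over the list alone (camera adjusted p = 1.51e-12, and adjusted p = 0.335 with an estimated correlation). Within replicates 1 and 2 alone 20 of 56 were higher, and within replicates 3 and 4 alone 34 of 52. The count was 15 without 2 mM replicate 2 or 4. MpLEA-like36 rose from 0.0612 ± 0.0741 to 23.0 ± 15.5 CPM, MpLEA-like35 from 0.163 ± 0.116 to 22.9 ± 17.5 and MpLEA-like34 from 0.0845 ± 0.169 to 11.97 ± 7.43. MpLEA-like39 was 578 times higher (95% counting interval 160.1 to 4776) and the catalase gene MpCAT1 596 times (165 to 4924). MpLEA2 rose 209-fold (log2 fold change 7.71 ± 1.26, edgeR adjusted p = 0.00409). Without 0 mM replicate 4 the log2 fold changes of MpLEA2, MpCAT1, MpLEA-like35 and MpLEA-like39 were 6.23, 7.50, 6.38 and 8.08 (from 7.71, 8.85, 7.05 and 8.82). That of MpLEA-like36 was 9.51 without 2 mM replicate 1 (from 8.45). MpLEA2 and MpLEA-like34 had counts at 2 mM in replicate 1 alone and MpCAT1 in replicate 4 alone. WRKY genes had 4 of 13 higher, 5 adjusted over the list alone (camera adjusted p = 3.04e-05, and adjusted p = 0.306 with an estimated correlation), with MpWRKY12 at 11.6 ± 3.07 and 35.7 ± 13.5 CPM and MpWRKY3 at 2.13 ± 0.781 and 27.8 ± 23.6 CPM. The WRKY count was 7 in the second set and 1 without any 2 mM library or 0 mM replicate 3 or 4, and edgeR called none in the first set. PKS/CHS genes had 1 of 21 higher, MpPKS/CHS12 (28.8 ± 2.27 to 175 ± 132 CPM), and 8 adjusted over the list alone (camera adjusted p = 6.71e-05, and adjusted p = 0.579 with an estimated correlation). Their median log2 fold change was 1.85, but 0.34 within replicates 1 and 2 alone, where edgeR called none, and 2.59 within replicates 3 and 4 alone, with 14 higher. The calls of MpPKS/CHS12 and MpWRKY3 were lost without any of the 4 libraries at 2 mM or 0 mM replicate 3 or 4 (edgeR adjusted p from 0.0561 to 0.0771 and from 0.0710 to 0.112). MpCYP821-like rose 10.4-fold in gpb1-2.

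In gpb1-2, 260 genes were higher and 326 lower at 0 mM (edgeR quasi-likelihood, Benjamini-Hochberg), 225 and 288 of them past the fold minimum. Named genes of this comparison had non-overlapping groups in 23 of 23 cases. Within replicates 1 and 2 alone 135 were higher and 231 lower, and within replicates 3 and 4 alone 1490 and 962. Counts moved to 163 higher without 2 mM replicate 1, 122 higher and 195 lower without replicate 2, 120 higher without replicate 3 and also without replicate 4, 197 lower without 0 mM replicate 2, and 106 higher and 184 lower without 0 mM replicate 4.

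Across the 13404 genes tested, the calcium responses of Tak-1 and gpb1-2, which share no library, had a Pearson correlation of 0.694 and a Spearman correlation of 0.619 (across genes, which are not independent replicates), with a slope of 0.543 for gpb1-2 on Tak-1. Among the genes called in Tak-1 the correlation was 0.864 and 95.2% had the same direction in gpb1-2. The lists shared 199 higher and 112 lower genes, where independent lists would share 22.9 and 15.01. Another 5 genes were higher in Tak-1 and lower in gpb1-2.

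The interaction contrast called 10 genes, all with a lower calcium response in gpb1-2 than in Tak-1. With a replicate block 7 of these were among 14 called. Of the 10, 4 are peroxidase genes. MpPOD51 was at 0.429 ± 0.0342 and 0.806 ± 0.282 CPM in Tak-1 at 2 and 0 mM. It was at 21.6 ± 8.74 and 2.90 ± 0.438 CPM in gpb1-2 (log2 interaction -3.80 ± 0.45, edgeR adjusted p = 0.00889). MpPOD138 (-4.74 ± 0.68), MpPOD28 (-2.94 ± 0.41) and MpPOD29 (-2.86 ± 0.44) followed with edgeR adjusted p from 0.0260 to 0.0366. The pathogenesis-related gene MpPR1w was at 0.868 ± 0.313 and 3.18 ± 2.08 CPM in Tak-1 and at 72.4 ± 39.5 and 8.77 ± 5.70 CPM in gpb1-2. The glycosyltransferase gene MpUGT28 was at 15.1 ± 1.26 and 24.1 ± 4.16 against 40.8 ± 1.94 and 30.3 ± 2.88 CPM. Mp5g22310 (-4.83 ± 0.77, and -3.94 without Tak-1 0 mM replicate 2) and Mp5g02060 (-3.45 ± 0.56) have no symbol.

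Over the 96 peroxidase genes the median log2 interaction was -2.35, with 84 below 0, 4 called and 26 adjusted over the list alone (camera adjusted p = 1.36e-21, and adjusted p = 0.0366 with an estimated correlation). It was -2.67 in the first set (25 of 108 called), no close pair in Tak-1 at 2 mM. In the second it was -1.43 (2 of 86). The GH19 genes (median -1.52, 5 of 12 lower adjusted over the list alone), the HA genes (-1.16, 4 of 15) and the NBS-LRR genes (-0.47, 6 of 21), which encode intracellular immune receptors, had no member past the threshold over all genes in edgeR, and 2, 2 and 3 in DESeq2. In the first set 1 GH19 gene, 2 HA genes and 2 NBS-LRR genes were lower and 1 HA gene higher, and in the second 1 GH19 gene was lower. Without Tak-1 2 mM replicate 1, edgeR called 5 GH19, 2 HA, 3 NBS-LRR and 13 peroxidase genes as lower. It called 1 GH19 gene without Tak-1 0 mM replicate 4 and 1 HA gene without gpb1-2 2 mM replicate 3. The 4 peroxidase calls dropped to 1 without Tak-1 2 mM replicate 2 or 4, Tak-1 0 mM replicate 3 or gpb1-2 replicate 2 at either level, and to 2 without Tak-1 0 mM replicate 1 or gpb1-2 0 mM replicate 3. Their camera calls (adjusted p = 1.18e-07, 0.00184 and 2.45e-05) held with an estimated correlation (adjusted p = 0.0366, 0.0370 and 0.0448 with an estimated correlation). Within replicates 3 and 4 alone the HA median was -0.25. In GH19 the groups had mean log2 CPM of 3.65 ± 0.65 in Tak-1 at 2 mM and 5.44 ± 0.45 at 0 mM, against 5.37 ± 0.26 and 5.44 ± 0.16 in gpb1-2.

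No gene had a higher response in gpb1-2 by edgeR, where 191 had an unadjusted p below 0.05 in that direction, and DESeq2 called 7 higher and 136 lower. Leaving out Tak-1 2 mM replicate 1 gave 186 lower and 2 higher, and leaving out gpb1-2 2 mM replicate 3 gave 1 higher. The 10 lower calls dropped to 1 without Tak-1 2 mM replicate 2 or 4, Tak-1 0 mM replicate 3, gpb1-2 2 mM replicate 2 or gpb1-2 0 mM replicate 2. They dropped to 2 without gpb1-2 0 mM replicate 3, to 3 without Tak-1 0 mM replicate 1, to 4 without Tak-1 2 mM replicate 3 or gpb1-2 2 mM replicate 1, to 5 without Tak-1 0 mM replicate 2 and to 6 without gpb1-2 0 mM replicate 1. Of the 8 named genes MpPOD51 kept its call in each of the 16 fits that leave out a library, and the other 7 lost it in at least 6 (edgeR adjusted p from 0.0503 to 0.137). Within replicates 1 and 2 alone 455 were higher and 530 lower, and within replicates 3 and 4 alone 1 and 29.

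**Figure D2:**
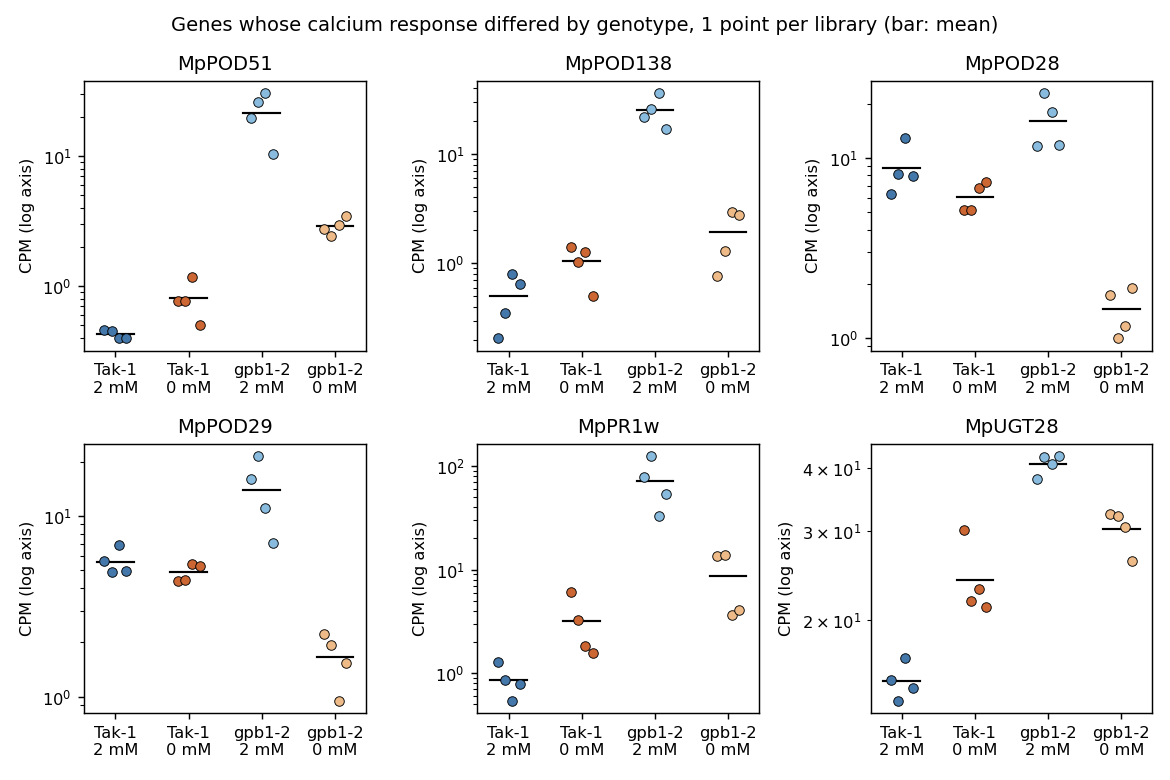
CPM on a log axis (y) of 6 genes with a lower calcium response in gpb1-2, in each library of the 4 groups (x axis, strain and calcium), with a bar at the group mean. MpPOD51 was at 21.6 CPM on average in gpb1-2 at 2 mM and at 2.90 or less in the other groups.

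At 2 mM calcium, more genes were higher than lower in gpb1-2 against Tak-1 over all libraries (213 and 55). Replicates 1 and 2 alone, no close pair in Tak-1, gave 967 and 1145. Peroxidase genes had 20 of 96 higher and 2 lower, and 40 and 2 adjusted over the list alone (camera adjusted p = 1.71e-13, and adjusted p = 0.183 with an estimated correlation). With replicates 1 and 2 alone 49 of 108 were higher (median log2 fold change 2.11), and with replicates 3 and 4 alone 21 of 86 (median 0.84). The 20 moved to 31 without Tak-1 replicate 1, 12 without Tak-1 replicate 2 or gpb1-2 replicate 1, 13 without Tak-1 replicate 3 or 4 and 11 without gpb1-2 replicate 2. MpPOD51 was 49.7-fold and MpPOD138 48.9-fold higher in gpb1-2, while MpPOD167 was lower at 169 ± 7.65 against 620 ± 145 CPM and MpPOD144 at 29.6 ± 6.89 against 69.1 ± 7.82 CPM. MpPOD34 was higher at 5.21 ± 2.53 against 0.0719 ± 0.0592 CPM. The pathogenesis-related genes MpPR1w (72.4 ± 39.5 against 0.868 ± 0.313 CPM) and MpPR1l (8.08 ± 5.92 CPM and no counts in Tak-1, at least 220.3-fold) were higher in the mutant. Chitinase genes of GH19 had 4 of 12 higher, and 6 higher and 1 lower adjusted over the list alone (camera adjusted p = 1.34e-05, and adjusted p = 0.135 with an estimated correlation), with MpGH19.13 at 522 ± 179.8 against 19.68 ± 16.0 CPM and MpGH19.5 at 14.7 ± 5.05 against 4.04 ± 1.88. The 4 were 3 in the first set and 7 in the second, with 1 lower in each, and dropped to 2 without Tak-1 replicate 2 or 3 or gpb1-2 replicate 1, 2 or 4. The log2 fold change of MpGH19.13 was 5.47 without Tak-1 replicate 1 (from 4.73). Dirigent genes had 4 of 40 higher, 5 adjusted over the list alone (camera adjusted p = 0.00243, and adjusted p = 0.560 with an estimated correlation), among them MpDIR48, 14.0-fold. This count was 10 in the first set, 7 in the second, 9 without Tak-1 replicate 1 and 1 without any other Tak-1 library or gpb1-2 replicate 1 or 2.

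Single genes also set the strains apart at 2 mM. Mp4g14850 had 14.1 ± 2.29 CPM in gpb1-2 and no counts in Tak-1 (at least 384-fold), and was likewise at 13.7 ± 1.80 CPM against no counts at 0 mM (at least 398-fold). The ammonium transporter gene MpAMT2.3 was at 0.980 ± 0.786 in gpb1-2 against 27.3 ± 14.8 CPM in Tak-1 (log2 fold change -4.81, or -5.44 without gpb1-2 replicate 3). The mutant also had more of the zinc finger gene MpC2H2-23 (38.9-fold) and of MpUGT28 (2.69-fold). It had less of the lipid transfer gene MpLTP-like65 (31.1 ± 12.5 against 164 ± 22.8 CPM), of MpCYP707A, of the family that breaks down abscisic acid (2.03 ± 0.187 against 7.46 ± 1.93), of MpCYP821-like (2.73 ± 0.957 against 9.75 ± 1.11) and of MpWRKY12 (11.6 ± 3.07 against 41.2 ± 10.01). In all, 213 genes were higher and 55 lower (edgeR quasi-likelihood, Benjamini-Hochberg), with 967 and 1145 within replicates 1 and 2 alone and 418 and 94 within replicates 3 and 4 alone. Counts moved to 498 higher without Tak-1 2 mM replicate 1, 90 higher and 26 lower without Tak-1 replicate 2, 102 and 31 without replicate 3, and 92 and 29 without replicate 4. They moved to 135 and 28 without gpb1-2 replicate 1, 113 and 29 without gpb1-2 replicate 2, and 84 lower without gpb1-2 replicate 3.

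The genotype effect at 2 mM and the calcium response of Tak-1 were compared to see whether the mutant in control medium was shifted toward the calcium-free wild type. Their correlation across genes was 0.518, but 50 simulations with no effect gave a mean of 0.505 from the shared Tak-1 2 mM libraries alone. The covariance was 0.409 against a simulated 0.0738, a difference of 0.335, and with the control libraries split between the comparisons the correlation was 0.422 on average over 6 splits (0.343 to 0.507). The lists shared 66 higher and 5 lower genes, in part through the shared libraries, for which no simulated count was made. Another 9 genes were lower in gpb1-2 and higher in Tak-1 without calcium, more than the 5 lower in both, and 6 the other way.

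At 0 mM the genotypes differed in few genes, 8 higher and 14 lower in gpb1-2 (edgeR quasi-likelihood, Benjamini-Hochberg). MpPOD167 was at 386 ± 41.5 against 1129 ± 174 CPM (log2 fold change -1.55 ± 0.16, edgeR adjusted p = 0.000453), and with Mp4g14850 it kept its call without each of the 8 libraries. A fit of only these groups with a replicate block called none of the 22 in edgeR (359 higher and 544 lower at an unadjusted p below 0.05), while DESeq2 without the block called 40 and 68. Replicates 1 and 2 against 3 and 4 differed in 1953 genes over the same libraries. MpAMT2.3, MpPOD28 and MpPOD22 were also lower (12.7-fold, 4.22-fold and 2.497-fold) and MpPOD51 was higher (3.58-fold). MpPOD28 lost its call without gpb1-2 replicate 2 or 3 (edgeR adjusted p from 0.0533 to 0.0554), MpAMT2.3 without gpb1-2 replicate 1, 2 or 3 or Tak-1 replicate 4 (0.0545 to 0.0991). MpPOD22 lost it without gpb1-2 replicate 2 or 3 or Tak-1 replicate 1 or 4 (0.0736 to 0.110) and MpPOD51 without any library but Tak-1 replicate 3 (0.0681 to 0.107). Camera called the LEA-like genes as higher and the PKS/CHS, POD and WRKY genes as lower (adjusted p = 0.0265, 0.0318, 0.00995 and 0.00184, each with adjusted p = 0.999 with an estimated correlation), with 1 member higher and 3 lower in POD and none past the threshold in the others. POD had 2 higher and 5 lower in the first set and 4 lower in the second. These calls were lost without Tak-1 replicate 3 or 4 or gpb1-2 replicate 4 for LEA-like (adjusted p from 0.342 to 0.975) and Tak-1 or gpb1-2 replicate 1 or 2 for PKS/CHS (0.139 to 0.510). They were lost without Tak-1 replicate 1 or 2 or gpb1-2 replicate 3 for POD (0.0780 to 0.185), and Tak-1 replicate 2 or gpb1-2 replicate 1 for WRKY (0.0554 to 0.103). The direction reversed within replicates 1 and 2 alone for LEA-like (adjusted p = 0.000730), and within replicates 3 and 4 alone for PKS/CHS (0.000947) and WRKY (0.303). Replicates 1 and 2 alone gave 133 higher and 239 lower, and replicates 3 and 4 alone 73 and 68. Leaving out a library moved the 8 higher genes to 1 (Tak-1 replicate 4, gpb1-2 replicate 2), 2 (Tak-1 replicate 1, gpb1-2 replicate 1 or 3), 3 (Tak-1 replicate 2) or 4 (Tak-1 replicate 3), and the 14 lower genes to 7 (gpb1-2 replicate 2), 8 (gpb1-2 replicate 3) or 9 (Tak-1 replicate 1).

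In Arabidopsis shoots, immune and jasmonate genes rose at 0 mM against 2 mM calcium. The pathogenesis-related gene PR1 (AT2G14610, chromosome 2, 6241640 to 6242541 in TAIR10.1), a marker of salicylic acid signalling, went from 21.3 ± 23.1 to 769 ± 293 CPM (SD, n = 4; log2 fold change 5.17 ± 0.84 SE, edgeR adjusted p = 0.00162), with a log2 fold change of 6.27 without 2 mM replicate 4. The glucanase gene BGL2 (AT3G57260) rose 18.2-fold and the salicylic acid exporter gene EDS5 (AT4G39030) 4.97-fold. Of the 20 genes of the salicylic acid list 18 rose, 20 adjusted over the list alone (camera adjusted p = 1.28e-08, and adjusted p = 0.197 with an estimated correlation). Of 28 jasmonate and wounding genes 27 rose, also 27 adjusted over the list alone, among them the repressor gene JAZ5 (AT1G17380, chromosome 1, 5955155 to 5957511), from 1.86 ± 0.707 to 32.5 ± 7.52 CPM, and the synthesis genes AOC3 (16.8-fold) and LOX3 (5.34-fold). Camera called this list (adjusted p = 4.29e-14, and adjusted p = 0.153 with an estimated correlation). The pattern-triggered immunity list had 13 of 20 higher, 15 adjusted over the list alone, with PROPEP3, the precursor of a danger peptide, at 0.165 ± 0.123 and 5.98 ± 1.48 CPM (log2 fold change 5.08, or 5.76 without 2 mM replicate 4) and WRKY6 at 18.1 ± 7.23 and 100.4 ± 16.8 CPM (camera adjusted p = 5.51e-07, and adjusted p = 0.195 with an estimated correlation).

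Among the largest rises in Arabidopsis were defence genes outside the salicylic acid list. CYP82C2 rose 113-fold, the plant defensin genes PDF1.3 (AT2G26010, chromosome 2, 11087280 to 11088001), PDF1.2b and PDF1.4 80.7-fold, 68.9-fold and 62.7-fold, the nitrilase gene NIT2 79.8-fold and the thionin gene THI2.1 58.1-fold. Defensin levels at 2 mM were uneven, with replicate 4 at 15.3 CPM for PDF1.3 and the others at 2.92 to 4.53 CPM. Without that library the log2 fold changes of CYP82C2, PDF1.3, PDF1.2b, NIT2 and THI2.1 were 7.95, 7.20, 7.34, 7.22 and 7.06 (from 6.82, 6.33, 6.11, 6.32 and 5.86). All 16 genes of the unfolded protein response list rose (camera adjusted p = 2.08e-09, and adjusted p = 0.116 with an estimated correlation; 16 adjusted over the list alone), led by the calreticulin gene CRT3 (AT1G08450, chromosome 1, 2667798 to 2671957; 64.2 ± 3.93 to 179.9 ± 14.9 CPM) and the chaperone gene BIP3 (8.11-fold). Senescence and cell death genes had 11 of 14 higher, 12 adjusted over the list alone (camera adjusted p = 3.62e-05, and adjusted p = 0.195 with an estimated correlation), with the metacaspase gene MC2 up 6.32-fold and NAC6, the transcription factor also called ORE1, 4.40-fold. Abscisic acid and dehydration genes had 10 of 19 higher, 10 adjusted over the list alone, including NCED3, of abscisic acid synthesis (5.05-fold), ADH1 (7.11-fold) and KIN1 (8.63-fold) (camera adjusted p = 0.00396, and adjusted p = 0.116 with an estimated correlation). Of 19 oxidative stress genes 10 rose and 2 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.000995, and adjusted p = 0.245 with an estimated correlation): the peroxidase gene PRXCB rose 9.83-fold and the superoxide dismutase gene CSD1 2.06-fold, while CSD2 fell 1.67-fold and the catalase gene CAT2 2.498-fold.

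Photosynthesis genes fell in Arabidopsis at 0 mM, in 37 of 38 list members and in all 38 adjusted over the list alone (camera adjusted p = 2.84e-13, and adjusted p = 0.245 with an estimated correlation). The Rubisco small subunit genes RBCS2B (AT5G38420, chromosome 5, 15380907 to 15382071) and RBCS3B fell from 3133 ± 469 to 819 ± 212 and from 6056 ± 1025 to 1922 ± 456 CPM, and PSBQA, of photosystem II, from 1927 ± 220.1 to 730.4 ± 162 CPM. Among 26 cell division genes 6 fell, 6 adjusted over the list alone, with the kinase genes AUR1 and CDKB1;2 1.83-fold and 1.81-fold lower (camera adjusted p = 0.340). The 4 named genes with the largest falls were NEET, an iron-sulfur protein gene (19.6-fold), ACS11, of the ethylene precursor synthases (16.9-fold), the wall enzyme gene XTH17 (8.24-fold) and SOB5 (7.53-fold, a log2 fold change of -2.91, or -4.13 without 0 mM replicate 1). Cell wall remodelling genes went both ways, 7 higher and 7 lower of 31, with the same counts adjusted over the list alone. The wall-associated kinase gene WAK1 and the inhibitor gene PGIP2 rose 4.69-fold and 4.68-fold, and the expansin gene EXPA5 fell 1.96-fold (camera adjusted p = 0.647; the median was -0.10 and the mean 0.25).

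Genes of calcium handling changed in both directions in Arabidopsis. Of 32 calcium transport genes 11 rose and 3 fell, with the same counts adjusted over the list alone. The annexin gene ANNAT1 (AT1G35720, chromosome 1, 13225168 to 13227239) rose from 60.1 ± 15.03 to 228 ± 13.3 CPM and the channel gene CNGC11 from 10.6 ± 4.23 to 62.1 ± 15.8, while the vacuolar calcium pump gene ACA4 fell from 198 ± 35.7 to 82.0 ± 21.7 and the channel genes MCA1 and DND1 fell 1.81-fold and 1.64-fold. DND1, whose groups overlapped, lost its call without 2 mM replicate 2 or 3 or 0 mM replicate 4 (edgeR adjusted p from 0.0509 to 0.0671). The list call (camera adjusted p = 0.0382, and adjusted p = 0.314 with an estimated correlation) was lost without 0 mM replicate 2, 3 or 4 (adjusted p from 0.0542 to 0.0660). Calcium sensing genes had 14 of 43 higher and 2 lower, 13 and 2 adjusted over the list alone (camera adjusted p = 0.00106, and adjusted p = 0.245 with an estimated correlation), with the calmodulin-like gene AT2G41090 3.47-fold and the kinase gene CIPK23 1.56-fold higher, and the sensor genes CBL9 and CBL10 1.64-fold and 1.38-fold lower.

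Of 9 heterotrimeric G protein genes in Arabidopsis, 2 rose and 2 fell, and adjusted over the list alone 4 rose and 2 fell (camera adjusted p = 0.190). RGS1 (AT3G26090, chromosome 3, 9532613 to 9535629), the regulator of G protein signalling, rose from 14.5 ± 1.66 to 30.5 ± 2.15 CPM and the extra-large alpha subunit gene XLG2 from 35.1 ± 5.12 to 56.0 ± 9.46. The gamma subunit gene AGG3 fell from 4.18 ± 0.839 to 1.96 ± 0.323 and XLG1 from 83.4 ± 4.76 to 59.4 ± 7.03 CPM. AGB1 (AT4G34460, chromosome 4, 16477031 to 16479620), the beta subunit gene, was at 87.5 ± 10.3 and 97.7 ± 3.07 CPM, not called in the fit without pairing (edgeR adjusted p = 0.253).

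Lists drawn from gene descriptions gave a wider view of the Arabidopsis response. WRKY factors, which regulate defence genes, had 41 of 59 higher and 2 lower, with WRKY28 up 5.31-fold and WRKY62 19.07-fold (camera adjusted p = 1.28e-10, and adjusted p = 0.116 with an estimated correlation). Among the other lists called as higher, members higher and lower were 86 and 13 of 197 pathogen defence proteins, 24 and 3 of 37 lipoxygenase and jasmonate genes, 27 and 6 of 49 class III peroxidases, 23 and 3 of 45 glutathione S-transferases, and 66 and 12 of 139 cytochrome P450 genes. Camera gave these adjusted p = 4.42e-06, 3.03e-07, 7.16e-05, 7.08e-06 and 4.85e-06 (adjusted p = 0.116, 0.132, 0.0850, 0.195 and 0.116 with an estimated correlation). GSTU8 rose 5.56-fold, CYP83B1, of glucosinolate synthesis, 3.97-fold, and the lipid transfer gene LTP2 7.92-fold. Lipid transfer proteins had 24 of 47 higher and 6 lower, phenylpropanoid and flavonoid synthesis 13 and 3 of 37 with CCR2 up 15.6-fold, calcium sensing and transport 94 and 25 of 274, LEA and dehydrin genes 15 and 4 of 48, and NAC factors 31 and 11 of 76. Their camera results were adjusted p = 0.000220, 0.00396, 5.94e-05, 0.00409 and 0.00320 (adjusted p = 0.132, 0.314, 0.116, 0.132 and 0.314 with an estimated correlation). AP2/ERF factors, with 15 of 41 higher and 8 lower (camera adjusted p = 0.0364, and adjusted p = 0.245 with an estimated correlation), lost their call without 2 mM replicate 4 (adjusted p = 0.0993).

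Of 312 ribosomal protein genes in Arabidopsis 137 fell and 4 rose, the lower including the plastid genes RPS1 (2.19-fold) and RPL9 (2.24-fold). Photosynthesis proteins fell in 60 of 69, and of 156 cell division proteins 41 fell and 8 rose. Camera called these 3 lists (adjusted p = 4.78e-12, 4.17e-17 and 0.00414, and adjusted p = 0.202, 0.206 and 0.116 with an estimated correlation). Phosphate starvation genes had 5 of 10 higher and 1 lower, with the phosphatase gene PS2 up 27.7-fold, the regulator gene SPX1 up 6.91-fold and the lipid synthesis gene SQD2 down 1.63-fold (camera adjusted p = 0.0476, and adjusted p = 0.394 with an estimated correlation). That call was lost without 2 mM replicate 1, 2 or 4 or 0 mM replicate 4 (adjusted p from 0.0576 to 0.0928). Heat shock genes had 3 of 10 higher, with DREB2A up 6.96-fold, and their call (camera adjusted p = 0.0305, and adjusted p = 0.340 with an estimated correlation) was lost without 2 mM replicate 1 or 4 or 0 mM replicate 3 (adjusted p from 0.0502 to 0.0958). Iron homeostasis genes had 4 of 18 higher and 4 lower, with the transporter gene IRT1 up 7.82-fold (log2 fold change 2.97, or 3.94 without 2 mM replicate 4) and the ferritin gene FER3 down 2.63-fold (camera adjusted p = 0.326). Camera called neither the description lists of cell wall enzymes (24 higher and 28 lower of 113), dirigent proteins (2 and 0 of 9), heat shock proteins (17 and 11 of 116) and MYB factors (34 and 14 of 105) nor those of receptor-like kinases (85 and 63 of 275) and phosphate starvation proteins (14 and 4 of 39). Their adjusted p was 0.890, 0.504, 0.325, 0.0661, 0.326 and 0.121. Adjusted over the list alone, the phosphate list had 6 higher and 2 lower, iron 4 and 4, heat shock 3 and 0, and of the description lists ribosomal proteins had 149 lower, photosynthesis proteins 61 lower and WRKY factors 41 higher and 2 lower.

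Over all Arabidopsis genes, 3881 were higher and 3773 lower at 0 mM (edgeR quasi-likelihood, Benjamini-Hochberg), and 2044 and 1018 of them differed at least 2-fold. Groups did not overlap in 64 of the 67 named genes, but the naming rule asked for this in part, so it is no support. Leaving out each of the 8 libraries in turn kept both counts within 1.5 times. With an estimated correlation camera called none of the lists, whereas fry called 13 of the 17 lists of codes and 18 of the 21 description lists. Root markers, which excised shoots should hold little of, had 3 tested members. EIR1 (0.522 ± 0.116 to 0.917 ± 0.179 CPM) and SHV2 (0.286 ± 0.243 to 0.862 ± 0.277 CPM) rose, with calls lost without 2 mM replicate 1, 2 or 3 or 0 mM replicate 1, 3 or 4 (edgeR adjusted p from 0.0696 to 0.102 and from 0.0712 to 0.110). The log2 fold change of SHV2 was 1.51, or 2.29 without 2 mM replicate 4. The list was not called (camera adjusted p = 0.504), and 2 rose and 1 fell adjusted over the list alone.

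**Figure D3:**
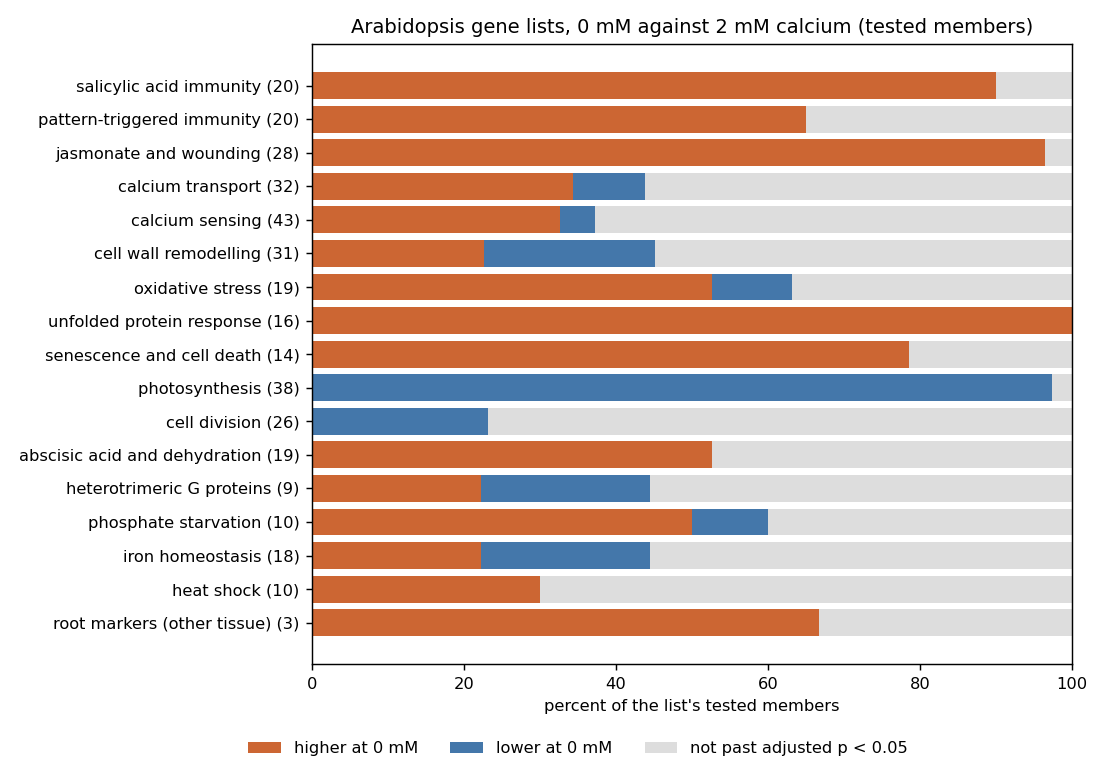
Percent of the tested members of 17 Arabidopsis gene lists (rows, with the number of members) that were higher, lower or not past an adjusted p of 0.05 at 0 mM against 2 mM calcium (x axis, edgeR). The jasmonate list had 27 of 28 members higher and the photosynthesis list 37 of 38 lower.

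**Figure D4:**
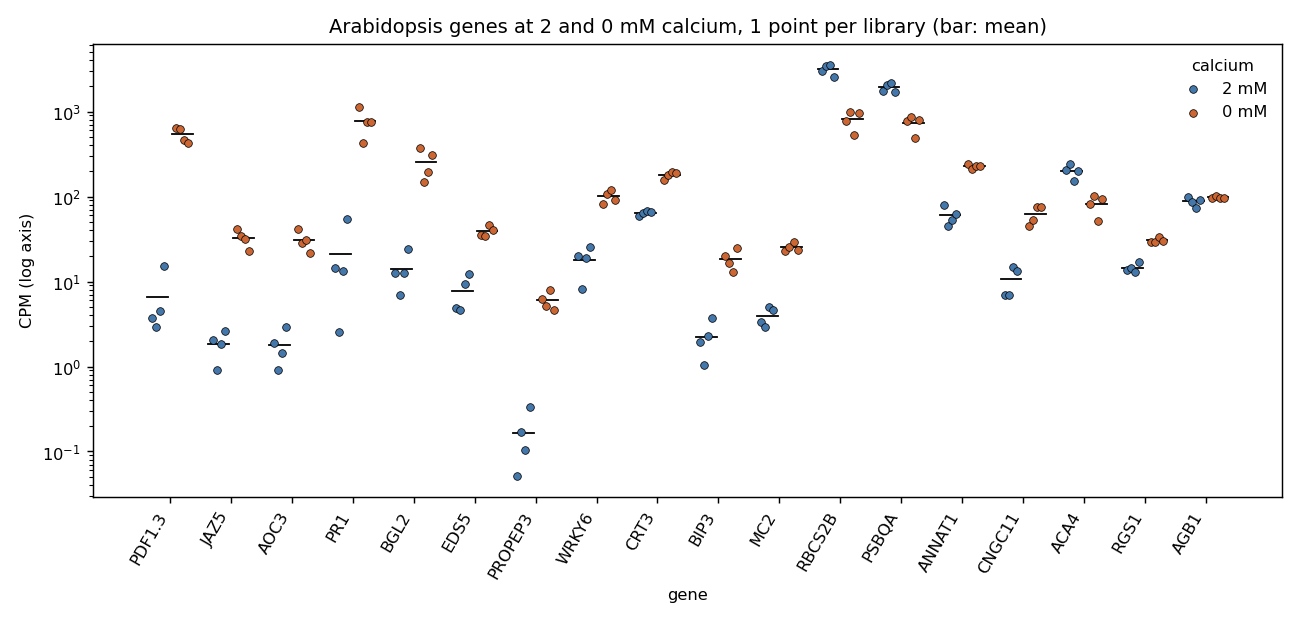
CPM on a log axis (y) of 18 Arabidopsis genes (x axis) in each of the 4 libraries at 2 mM and the 4 at 0 mM calcium, with a bar at each group mean. PR1 was at 21.3 and 769 CPM on average, RBCS2B at 3133 and 819, and AGB1 at 87.5 and 97.7.

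In lettuce shoots at 0.15 mM against 2 mM calcium, 5555 genes were higher and 3496 lower (edgeR quasi-likelihood, Benjamini-Hochberg), of which 3249 and 875 differed at least 2-fold. The genes with the largest rise, LOC111915189 and LOC111878912, had no counts in the 3 control libraries and 724.5 ± 419 and 232 ± 197 CPM at 0.15 mM (SD, n = 3), at least 16957-fold and 5421-fold higher, and the estimate for LOC111878912 was 1.85 times smaller without 0.15 mM replicate 1. LOC111880531 fell from 22.0 ± 2.43 to 2.33 ± 1.23 CPM (log2 fold change -3.24 ± 0.36, edgeR adjusted p = 0.000733) and LOC111892004 from 28.7 ± 9.93 to 3.15 ± 2.17 CPM (-3.20 ± 0.60, edgeR adjusted p = 0.00575). Without gene names no gene groups were tested in lettuce. The count of lower genes dropped to 2028, 2238 and 1986 without control replicate 1, 2 or 3.

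Genes listed in the authors' deposited tables were set beside these fits, as the same libraries processed by other hands. The authors' deposited table for Arabidopsis holds 1012 higher and 128 lower genes, and 1092 of the 1097 tested here passed in the same direction (99.5%). In the authors' deposited table for lettuce (2014 higher, 60 lower) this held for all 1955 tested. In the authors' deposited tables for the liverwort it held for 584 of 646 in Tak-1 (90.4%), 326 of 534 in gpb1-2 (61.0%) and 167 of 298 for the genotypes at 2 mM (56.0%). No gene of the authors' deposited tables passed here in the opposite direction, and the log2 fold changes correlated at 0.983 to 0.998 across the listed genes.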

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

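The tests of the replicate sets, of the single library, of the peroxidase family and of other groupings of the samples below were chosen after the results they concern were seen, whereas the interaction test was planned.

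Libraries far from the others of their group were sought with Dixon's ratio of the gap to the range, where chance marks about 1 in 20 groups. None of 6 groups was marked by library totals, 3 of 74 by gene list scores (4.05%) and 25 of 290 by named genes (8.62%), and 10 of these lay in replicate 1 of Tak-1 at 2 mM. In that library the dirigent (DIR) score was 2.90 against 1.64 to 1.74 (ratio 0.921). MpPKS/CHS14 was at 84.8 CPM against 29.7 to 34.4 (0.915), MpPKS/CHS10 at 65.4 against 12.8 to 17.3 (0.915), MpWRKY3 at 6.30 against 0.201 to 0.595 (0.935), MpDIR56 at 24.7 against 6.76 to 8.43 (0.907), MpDIR51 at 4.54 against 0.0502 to 0.744 (0.846) and MpGST27 at 15.1 against 9.27 to 10.2 (0.848). MpLEA-like37 was at 0.103 with no counts in the others (ratio 1), while MpMCM6 was lowest at 11.7 against 19.4 to 20.5 (0.873) and MpCYP821-like lowest at 8.10 against 10.14 to 10.5 (0.863).

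Replicate 4 of gpb1-2 at 0 mM was highest for MpCAT1 at 33.7 CPM against 3.05 to 6.62 (ratio 0.884), MpLEA2 at 34.5 against 2.53 to 5.10 (0.920), MpLEA-like36 at 46.2 against 13.2 to 17.2 (0.879) and MpLEA-like35 at 48.9 against 10.4 to 16.9 (0.830). For genes seen in a single library of a group the ratio is 1, as for MpLEA2 in Tak-1 2 mM replicate 3 and gpb1-2 2 mM replicate 1, MpLEA-like34 in gpb1-2 2 mM replicate 1, MpCAT1 in gpb1-2 2 mM replicate 4 and MpPOD34 in gpb1-2 0 mM replicate 1. The WRKY score was lowest in gpb1-2 2 mM replicate 2, at 3.98 against 4.13 to 4.16 (0.844). In Arabidopsis, 2 mM replicate 4 was highest for PDF1.3 (15.3 CPM against 2.92 to 4.53, 0.870), PDF1.2b (4.62 against 0.558 to 1.19, 0.846) and THI2.1 (1.08 against 0.152 to 0.258, 0.887). The others were the G protein score in 2 mM replicate 2 (4.78 against 4.69, 0.963), WRKY62 in 2 mM replicate 3 (0.833), RBCS3B in 0 mM replicate 3 (1242 CPM against 2093 to 2206, 0.882), CSD1 in 0 mM replicate 4 (0.857) and EXPA5 in 0 mM replicate 2 (0.971). No explanation was tested for the marks in this paragraph.

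Replicate 1 of Tak-1 at 2 mM was weighed first. An exchange with a 0 mM library was excluded, since a score from genes called in gpb1-2 was 2.60 or more in each Tak-1 0 mM library and 0.569 or less in each 2 mM library, a gap of 2.03. Mixing with 0 mM RNA needed a 3.43% share from LEA-like (1.93% to 13.2% by donor library) and 0.976% from GH19 genes. PKS/CHS genes needed 23.8% (17.5% to 41.2%), WRKY 20.6%, DIR 30.1% and GST 30.04%, so mixing alone was argued against. The test limit was set after these shares were seen. A difference in the state of these gemmalings may remain, which the labels cannot test.

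Replicates 1 and 2 of the liverwort lay apart from replicates 3 and 4 in 3 of the 4 groups, where each pair across the sets was further apart than each pair within a set. In Tak-1 at 2 mM replicate 1 alone stood apart. The difference between the sets correlated between groups at 0.199 to 0.668 across genes, and with the calcium response of the other genotype at 0.261 and 0.379 in Tak-1 at 2 and 0 mM and 0.487 and -0.0370 in gpb1-2. A culture or library batch shared by the 4 groups, or plants in different states, may lie behind it. These values do not decide, since the correlations restate the pattern and the labels name no batch. Library size was argued against, because 7 of the 8 libraries of replicates 3 and 4 had totals within the range of replicates 1 and 2. The groupings of samples showed the same structure: replicates 1 and 2 against 3 and 4 gave 3283 genes among the gpb1-2 libraries, several times the real 586, and 1953 among the libraries at 0 mM, against a real 22.

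The calcium response differed between the genotypes in an interaction test for MpPOD51 (log2 -3.80), MpPOD138 (-4.74), MpPOD28 (-2.94), MpPOD29 (-2.86), MpPR1w (-4.92), MpUGT28 (-1.09), Mp5g22310 (-4.83) and Mp5g02060 (-3.45), and for Mp7g05420 (-3.14) and Mp7g00770 (-1.41), which lie outside the naming rule and were chosen after their values were seen. Family medians were -2.35 for POD, -1.52 for GH19, -1.16 for HA and -0.47 for NBS-LRR.

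For the peroxidase family, a scaling factor per library would move all genes alike. Scaling was argued against because the family median lay at -2.36 from the median of all tested genes (0.02), which was also above the third quartile of the family (-0.85). RLE size factors moved the values too little to decide, and this test was taken up after that was seen. The replicate sets as the whole cause were argued against by -1.43 in the set with the smaller effect. Reads passed between neighbouring paralogs may have a part and stay open. The sum over all 68 neighbouring members overlapped between media in gpb1-2 (2522 ± 796 and 3189 ± 245 CPM) and by its own prediction went with that explanation. A form limited to the 17 stretches of neighbours with a called member (14 with a higher sum in each 2 mM library than in each 0 mM library) used genes chosen for the pattern and decides nothing. Of all 22 stretches with at least 2 tested members, a form set up last, the sum was higher in each 2 mM library in 11 and lower in 1. The missing G protein beta subunit, which the design names, stays open as well, and hour of harvest, which follows the medium, was not tested.

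Over other groupings of the same samples, chance was excluded for Tak-1 (1 of 35 groupings gave as many genes, 1800 against 1471 in the highest other), for the genotypes at 2 mM (1 of 35, 268 against 37) and for the interaction (1 of 35 that keep the libraries of the same strain and number together, 10 against 1, and 1 of 60 drawn without regard to number, 10 against 2). The highest other grouping in Tak-1 put 2 mM replicate 1 with 0 mM replicates 1, 2 and 3. For the genotypes at 0 mM 3 of 35 groupings gave as many genes (22 against 1953 in the highest other). The numbers pair the samples in Arabidopsis, and the 8 groupings that part each number are too few for a share under 0.05, with 7654 genes for the real one (1 of 8) and 0 for the highest other. The groupings that leave pairs together gave up to 11. For gpb1-2 the numbers do not clearly pair the samples. Over all groupings the real one did not give the most (2 of 35 gave as many genes, 586 against 3283). The 8 that part each number are again too few (1 of 8, highest other 0). For lettuce 10 groupings are too few for a share under 0.05, with 9051 genes for the real one (1 of 10) and 0 for the highest other.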

How the results depend on the processing

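The fold minimum inside the tests, the fits of replicate sets and the fits of only the groups compared with a replicate block were chosen after the data were seen, and the other settings were planned. Where no cause is named below, the cause was not tested.

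Counts are given as higher and lower genes. With DESeq2, which called all genes that edgeR called in each liverwort comparison (1800, 586, 268, 22 and 10 shared), higher genes in Tak-1 came to 1856, gpb1-2 had 644 and 591, the genotypes at 2 mM 606 and 183, the genotypes at 0 mM 40 and 68, and the interaction 7 and 136. RLE size factors and the stricter filter of 1 CPM kept each count of genes within 1.5 times, as did a robust fit for the interaction, and no count filter did so but for 5 higher genes between the genotypes at 0 mM.

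In edgeR a fold minimum leaves fewer genes by construction. Applied to the called genes it gave 2044 and 1018 in Arabidopsis, 3249 and 875 in lettuce and 388 lower in Tak-1. Inside the edgeR test it gave 937 and 145 in Arabidopsis, 2119 and 107 in lettuce, 355 and 55 in Tak-1, 81 and 141 in gpb1-2, 103 and 20 for the genotypes at 2 mM, 2 and 8 at 0 mM, and 3 lower for the interaction. With DESeq2, where tool and minimum changed together, it gave 834 and 76 in Arabidopsis, 2000 and 57 in lettuce, 490 and 57 in Tak-1, 125 and 172 in gpb1-2, 25 lower for the genotypes at 2 mM, and 1 and 27 for the interaction.

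Fits of only the groups compared, with fewer samples to estimate the spread, gave 378 lower in Tak-1, 216 lower in gpb1-2, and 3 and 9 for the genotypes at 0 mM. With a replicate block as well they gave 756 and 232 in Tak-1, 57 and 21 for the genotypes at 2 mM, and 0 and 0 at 0 mM (edgeR, with 359 higher and 544 lower at an unadjusted p below 0.05, and 40 and 68 called by DESeq2 without the block). The replicate block over all 16 libraries gave 26 lower at 0 mM. It also gave 1291 lower in Tak-1 and 448 and 188 for the genotypes at 2 mM. In Arabidopsis, where the numbers pair the samples, and in gpb1-2, where they may or may not, the block moved no count by over 1.5 times. The genes changed more: in gpb1-2, 538 of the 586 were among 805 with the block over all libraries and 336 among 664 in the fit of its own groups with a block, while in Arabidopsis 7611 of the 7654 were among 10077.

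A term for the replicate sets gave 1999 and 1782 in Tak-1, 605 and 568 in gpb1-2, 639 and 350 for the genotypes at 2 mM, 21 and 44 at 0 mM, and 1 and 48 for the interaction. Replicates 1 and 2 alone gave 2062 and 1952 in Tak-1, 135 higher in gpb1-2, 967 and 1145 for the genotypes at 2 mM, 133 and 239 at 0 mM, and 455 and 530 for the interaction. Replicates 3 and 4 alone gave 189 lower in Tak-1, 1490 and 962 in gpb1-2, 418 and 94 for the genotypes at 2 mM, 73 and 68 at 0 mM, and 1 and 29 for the interaction.

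Leaving out each library in turn gave 457 to 1609 higher and 129 to 932 lower in Tak-1, 106 to 338 and 184 to 278 in gpb1-2, 90 to 498 and 26 to 84 for the genotypes at 2 mM, 1 to 6 and 7 to 14 at 0 mM, and 0 to 2 and 1 to 186 for the interaction. The ranges were 3198 to 3796 and 2877 to 3636 in Arabidopsis and 4065 to 5750 and 1986 to 4099 in lettuce. The libraries behind the moves are named with each comparison.

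Camera with an estimated correlation called 0 lists in each comparison but the interaction, where it called 4. Fry called 4 for the interaction and 0 for the genotypes at 0 mM. The correlation of the calcium responses was 0.864 over genes called in Tak-1 and 0.800 over genes called in either strain, and that of the genotype effect with the Tak-1 response was 0.422 on average with the controls split.

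Some list results changed direction. For the genotypes at 0 mM these were LEA-like in replicates 1 and 2 alone (adjusted p = 0.000730) and PKS/CHS and WRKY in replicates 3 and 4 alone (0.000947 and 0.303). For the interaction they were ABCC and PPR in replicates 3 and 4 alone (0.558 and 0.441). Over all settings, single genes and lists had 7188 values with the same direction and side of the threshold, 1321 with the same direction and no longer past it, 11 newly past it and these 5. Overlaps between species were not run.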

Other observations

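The families in this part were tested as planned for all families with at least 10 members, and were picked for this part after their results were seen.

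In Tak-1, camera also called the glycosyltransferase family UGT as higher (5 of 29 higher, adjusted p = 0.0362, and adjusted p = 0.491 with an estimated correlation) and the TRIHELIX transcription factors (4 of 35 lower, adjusted p = 0.0293) and HAT genes (2 of 12 lower, adjusted p = 0.0472) as lower, both with adjusted p = 0.491 with an estimated correlation. In the first set (replicates 1 and 2 alone) UGT had 10 higher and 3 lower, TRIHELIX 6 lower and 2 higher, and HAT 1 of each, and in the second (replicates 3 and 4 alone) UGT had 3 higher. Without 2 mM replicate 2, 3 or 4 or 0 mM replicate 1 or 2 UGT had 3 higher and the 4 TRIHELIX genes were lost. HAT had 1 or fewer lower without any library but 2 mM replicate 1 or 0 mM replicate 3. The UGT call was lost without 2 mM replicate 1 or 0 mM replicate 3 (adjusted p from 0.105 to 0.112). TRIHELIX lost its call without 2 mM replicate 4 or 0 mM replicate 3 or 4 (0.0591 to 0.120), and HAT without 2 mM replicate 3 or 4 or 0 mM replicate 1, 3 or 4 (0.0573 to 0.133).

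In gpb1-2, NBS-LRR immune receptor genes were, among others, called as lower (1 of 21 lower, adjusted p = 0.00544, and adjusted p = 0.287 with an estimated correlation), a call lost without 0 mM replicate 1 (adjusted p = 0.0693). The NBS-LRR gene was lost without any library but 2 mM replicate 4, and 1 was lower in the first set and 2 in the second. ABCB transporter genes had 2 of 10 higher (1 in the first set, 3 in the second, and 1 without 2 mM replicate 1 or 2 or 0 mM replicate 4; adjusted p = 0.0461, and adjusted p = 0.287 with an estimated correlation), lost without 2 mM replicate 1, 2 or 4 or 0 mM replicate 1 or 3 (0.0599 to 0.101).

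Between the genotypes at 2 mM, camera called, among others, NBS-LRR (1 of 21 higher, 6 adjusted over the list alone) and PKS/CHS (none higher, 1 adjusted over the list alone) as higher in gpb1-2 (adjusted p = 0.00459 for each, and adjusted p = 0.340 and 0.560 with an estimated correlation). The count for PKS/CHS hangs on Tak-1 replicate 1, without which 8 of 21 were higher and the median went from 0.54 to 1.80. It was 1 without gpb1-2 replicate 3, 1 in the first set and 9 in the second. The NBS-LRR count was 2 without Tak-1 replicate 1 and 1 without gpb1-2 replicate 3, and the member was lost without any of the other 6 libraries. It was 2 in each set, with 2 lower in the first.

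For the interaction, camera called PKS/CHS (median -1.10), DIR (-0.65) and Cupin (-1.47) as lower (adjusted p = 5.14e-06, 0.000684 and 0.000976, and adjusted p = 0.390, 0.437 and 0.130 with an estimated correlation). Expansin, GT37, ABCC and GH16 were called as lower and HAT and PPR as higher with adjusted p from 0.0131 to 0.0283 (from 0.390 to 0.616 with an estimated correlation). Within replicates 3 and 4 alone the direction reversed for ABCC and PPR (adjusted p = 0.558 and 0.441), and the PKS/CHS median was -0.58, against -2.28 within replicates 1 and 2. Calls were lost for Expansin without Tak-1 0 mM replicate 1 or gpb1-2 2 mM replicate 2 (0.0536 to 0.0784) and for GT37 without Tak-1 replicate 2 at either level or gpb1-2 0 mM replicate 3 (0.0514 to 0.0633). ABCC lost it without Tak-1 0 mM replicate 1, gpb1-2 2 mM replicate 1 or 2 or gpb1-2 0 mM replicate 3 (0.0521 to 0.0784), and HAT without replicate 4 of Tak-1 at either level, gpb1-2 2 mM replicate 2 or gpb1-2 0 mM replicate 3 (0.0653 to 0.120). GH16 lost it without those 4 libraries or gpb1-2 0 mM replicate 4 (0.0581 to 0.125), and PPR without Tak-1 0 mM or gpb1-2 2 mM replicate 1 or 2 or gpb1-2 0 mM replicate 3 or 4 (0.0568 to 0.252).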
